A study of Gallus gallus with 12 samples.

How the data were processed

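Methylated DNA immunoprecipitation sequencing (MeDIP-seq) pulls down fragments of genomic DNA with an antibody against methylated cytosine and sequences what is recovered. It was applied to liver DNA of chickens recorded as resistant or as susceptible to avian leukosis virus subgroup J (ALV-J), a retrovirus of chickens. Each group held 3 immunoprecipitated libraries, and 6 input libraries, made from DNA without immunoprecipitation, carried the same sample numbers in their labels. Groups were taken from the source label of each sample. Within a group, libraries are called replicates 1, 2 and 3 in order of deposition, and these numbers pair no samples. The sample numbers differ, but the labels do not say outright that each is a separate bird. P-values of comparisons between libraries therefore measure the spread between these samples.

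Per the labels' protocols, DNA was isolated from frozen liver with phenol and chloroform and sequenced as read pairs on an Illumina HiSeq instrument. The submitters' processing notes name cutadapt, Bowtie2 and the genome build galGal4. The authors deposited 1 peak list per immunoprecipitated library. The names of the lists and of their peaks record that each library was called on its own with MACS against the input of the same sample number, so replicates were not pooled. Tool versions, read filters and the handling of duplicate reads are not given in the sources used here. The deposited score of a peak ran from 80.0 to 3233.06 and was read, from its values, as the negative log10 of the caller's p-value multiplied by 10, which puts the authors' threshold at p = 1e-08. This score is the authors' own and rises with sequencing depth. It was therefore used mainly to rank or describe peaks within a list. A common score minimum was applied across lists in 1 alternative and in 1 test of peaks on Z, and both depend on depth. Read numbers are not part of a peak list, so depth is unknown, and a position without a peak is one where no peak passed the authors' threshold, not one shown to be unmethylated.

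Positions are given on galGal4, counted from 1. The gene table at hand was built on another assembly, GRCg7b, and coordinates were not carried between builds. Promoters, exons, introns, CpG islands and 14 gene lists that had been planned are therefore not analysed here, and regions are given by position without gene names. The length of a chromosome was taken as the highest peak end in any of the 6 lists, which is a lower bound. The 31 chromosomes and linkage groups with peaks summed to 1003.74 Mb.

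Peak number, covered length, peak width and covered length per Mb were compared between groups with exact two-sided permutation tests of the difference of means. With 3 libraries against 3 the smallest p such a test can give is 0.1, so no single comparison could pass 0.05. Chromosomes were classed as macrochromosomes (1 to 5), intermediate chromosomes (6 to 10), microchromosomes (11 to 28), Z and W, and p-values over the 5 classes, and separately over the 31 chromosomes, were adjusted by the Benjamini-Hochberg method. The similarity of a pair of libraries was the Jaccard index, the length covered in both divided by the length covered in either. The mean index within groups minus that between groups was set against all 10 splits of the libraries into 3 and 3.

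Overlapping or touching peaks of the 6 lists were merged into regions with bedtools, and a library counted as present where it had a peak in the region. A resistant-only region had a peak in all 3 resistant libraries and in 0 susceptible libraries, and a susceptible-only region the reverse. Regions with a peak in exactly 3 libraries served as background, since each of them could have followed the groups. No test was made per region. Confidence intervals of shares are exact Clopper-Pearson intervals at 95% and cover counting error only. The comparisons of peak number, covered length, chromosome classes, similarity and group-only regions and the rule for named regions were fixed before the data were examined. The tests of width and of single chromosomes had not been listed among them. By that rule, group-only regions were ranked within each direction by the lowest of their 3 libraries' score percentiles, each taken within the library's own list, and the 10 highest-ranked were named.

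The alternatives were a score minimum at the pooled median of 193.59, the 55599 highest-scoring peaks of every list, leaving out each library in turn, leaving out Z, W and unplaced sequence, a peak cover of at least 50% of a region, joining peaks up to 500 bp apart, fixed windows of 1000 bp, and for similarity the share of overlapping peaks and a reciprocal overlap of 50%. The use of only the 4 libraries with low Z coverage was added after seeing the data. On simulated lists with 67775 regions, in which 200 resistant-only and 100 susceptible-only regions had been planted, all 200 and 100 were recovered. The simulated regions lay apart from each other, and no unplanted region followed the groups. Full recovery was therefore fixed by construction. It checks the code only and does not measure missed or false regions in the real lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1 were used.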

Results

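Methylation-enriched regions were mapped in the liver of chickens resistant (3 libraries) and susceptible (3 libraries) to ALV-J, to examine whether DNA methylation differed between the groups. The resistant libraries held 64559, 61753 and 56120 peaks in replicates 1 to 3, and the susceptible libraries 55759, 62534 and 55599. Sequencing depth is unknown for every library. Peaks covered between 4.06% and 4.70% of the chromosome length that could be measured from the lists.

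In both groups peak coverage per Mb was highest on small chromosomes. CpG content was not analysed, so higher coverage need not mean that a larger share of CpGs was methylated. Not all small chromosomes stood equally high, and chromosome 22 had 105 ± 3.00 kb per Mb. Peaks covered 332 ± 9.60 kb per Mb on chromosome 25, 213 ± 6.53 kb per Mb on chromosome 28 and 223 ± 15.5 kb per Mb on chromosome 16, which carries the chicken major histocompatibility complex (mean ± SD, n = 6 libraries). On the large chromosomes 1 and 2 the corresponding values were 26.3 ± 1.29 and 21.0 ± 1.09 kb per Mb. The coverage of chromosome 16 rests on a measured length of only 0.531 Mb. Among the regions merged from all 6 lists, 30195 of 90181 (33.5%) had a peak in every library, and 22858 (25.3%) had one in a single library. Regions common to all 6 libraries spanned 39.2 Mb of the 71.5 Mb covered in any.

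The amount of methylation-enriched DNA was compared first. Resistant libraries held 60811 ± 4298 peaks covering 44.8 ± 1.06 Mb, and susceptible libraries 57964 ± 3959 peaks covering 44.4 ± 3.27 Mb (mean ± SD, n = 3 each). Mean peak width was 739 ± 63.6 bp in resistant and 768 ± 69.8 bp in susceptible libraries. The widest means were those of resistant replicate 3 (812 bp) and susceptible replicate 3 (848 bp), and the other libraries had 699 to 731 bp. These group differences lay within the spread between replicates (exact permutation test, two-sided, p = 0.5 for peak number, 0.9 for covered length and 0.5 for width). With the same number of peaks taken from every list, the difference in covered length changed sign, to -0.791 Mb. Without susceptible replicate 1 it was -1.44 Mb, and without resistant replicate 3 it was -0.0456 Mb. The difference in width changed sign without susceptible replicate 3, to 11.5 bp.

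The distribution over chromosome classes was compared next. Macrochromosomes were covered at 25.3 ± 1.17 kb per Mb in resistant and 25.1 ± 1.56 kb per Mb in susceptible libraries (exact p = 1). Intermediate chromosomes had 49.96 ± 1.57 and 49.1 ± 3.03 kb per Mb (exact p = 0.8), and microchromosomes 108 ± 1.77 and 107 ± 5.40 kb per Mb (exact p = 0.9). All adjusted p-values over the 5 classes were 1. The direction in these 3 autosome classes did not hold, since with the same number of peaks from every list the resistant minus susceptible differences were -0.694, -0.643 and -0.976 kb per Mb in the same order, and without susceptible replicate 1 they were -0.657, -0.856 and -2.00 kb per Mb. On chromosome 16 the coverage was 215 ± 4.21 kb per Mb in resistant and 231 ± 19.6 kb per Mb in susceptible libraries, a difference of -16.4 kb per Mb (n = 3 each, exact p = 0.2, adjusted p = 1 over 31 chromosomes). Without susceptible replicate 2 this difference was -5.41 kb per Mb.

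**Figure D1:**
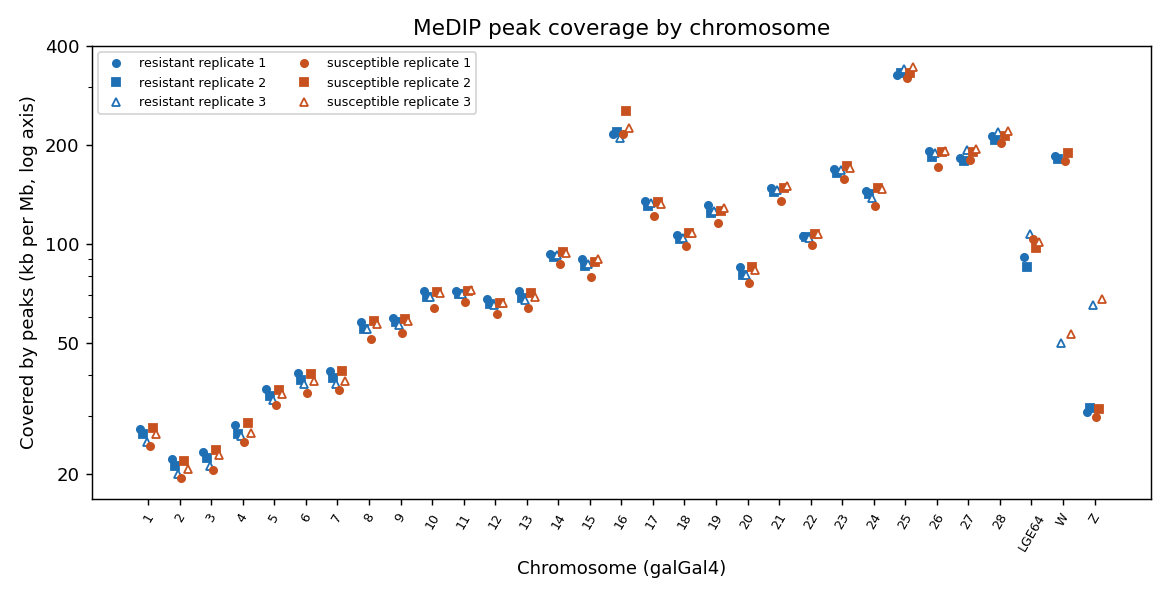
Covered length per Mb (kb, log axis) for each chromosome, with 1 point per library and the groups in different colours. The small chromosomes stand highest, with chromosome 25 at 332 kb per Mb as the mean of the 6 libraries, and libraries lie far apart on Z and W.

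The sex chromosomes separated individual libraries within each group. Male birds carry a pair of Z chromosomes and female birds 1 Z and 1 W, and the labels give no sex. On Z, peaks covered 30.9, 31.8 and 65.3 kb per Mb in resistant replicates 1 to 3 and 29.9, 31.7 and 68.1 kb per Mb in susceptible replicates 1 to 3. The library highest on Z was the lowest on W in each group, with 185, 181 and 50.2 kb per Mb in the resistant and 179, 189 and 53.3 kb per Mb in the susceptible libraries, in the same replicate order. Because 1 library of each group stood apart, the group values were 42.7 ± 19.6 against 43.2 ± 21.6 kb per Mb on Z (exact p = 0.9) and 139 ± 76.9 against 140.4 ± 75.6 kb per Mb on W (exact p = 0.8), with n = 3 each. Their differences changed sign when single libraries were left out, ranging from -11.8 to 11.9 kb per Mb on Z and from -45.0 to 43.0 kb per Mb on W. Covered length outside Z and W was 41.1 ± 1.15 Mb in resistant and 40.7 ± 2.26 Mb in susceptible libraries (n = 3 each, exact p = 0.9).

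Along Z, a block near 27 Mb showed the highest ratio between libraries among well-covered windows of 1000 kb (at least 20 kb in each of the 2 libraries with high Z coverage). In the window from 27000001 to 28000000, peaks covered 223 kb in resistant replicate 3 and 198 kb in susceptible replicate 3. The other libraries had 24.4 and 13.6 kb (resistant replicates 1 and 2) and 12.2 and 15.2 kb (susceptible replicates 1 and 2). Between 27200001 and 27300000, peaks covered 57.1 kb in resistant replicate 3 and 50.2 kb in susceptible replicate 3, and 0 kb in each of the other libraries. The window was singled out after its values were seen.

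**Figure D2:**
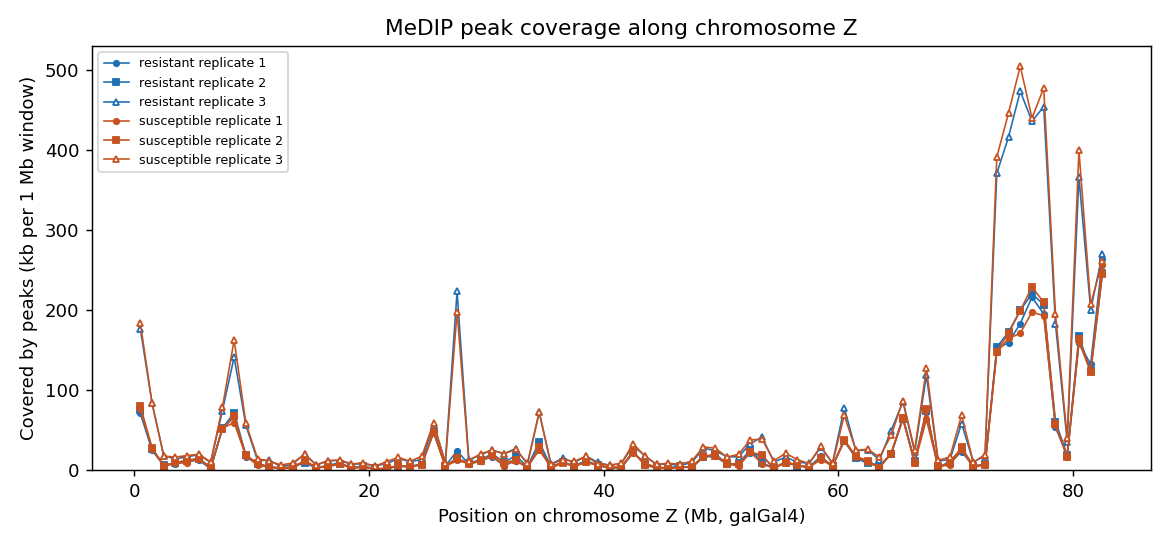
Covered length (kb) in windows of 1 Mb along chromosome Z on galGal4, with 1 line per library. Resistant replicate 3 and susceptible replicate 3 run above the other libraries along most of Z, with 223 and 198 kb in the window starting at 27 Mb.

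Over all 6 libraries, those of the same group were on average no more alike than those of different groups. The Jaccard index was 0.620 ± 0.0146 among resistant pairs (n = 3 pairs), 0.623 ± 0.0207 among susceptible pairs (n = 3 pairs) and 0.630 ± 0.0191 between groups (n = 9 pairs). The most similar pair was resistant replicate 3 with susceptible replicate 3, at 0.657. Within-group minus between-group similarity was -0.00777, and 7 of the 10 splits of the libraries gave a value as large (exact, over all splits, p = 0.7). These 7 include the 4 splits that put resistant replicate 3 and susceptible replicate 3, the libraries with high Z coverage, on the same side. Without Z and W the most similar pair was resistant replicate 2 with susceptible replicate 1, at 0.649. Resistant replicate 3 with susceptible replicate 3 had 0.646. The mean indices were then 0.633, 0.638 and 0.637, and the difference shrank to -0.00130. In the 4 libraries with low Z coverage, an alternative chosen after seeing the data, it changed sign, to 0.00123.

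**Figure D3:**
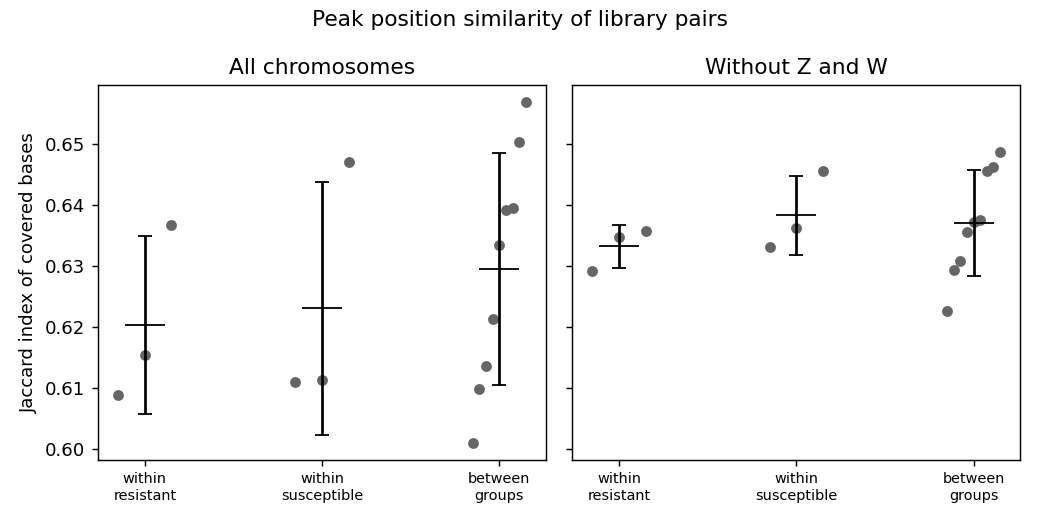
Jaccard index of covered length, with 1 point per pair of libraries and lines for mean ± SD, over all chromosomes (left) and without Z and W (right). Pairs within and between groups overlap in range, and the highest value over all chromosomes, 0.657, joins resistant replicate 3 and susceptible replicate 3.

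Few regions separated the groups completely. A peak in all 3 resistant and 0 susceptible libraries was found in 520 regions, and the reverse in 289 regions, which were 0.577% and 0.321% of all regions. With the 55599 highest-scoring peaks of every list the counts were 352 and 397, so that the direction turned. It also turned in fixed windows of 1000 bp (236 and 254) and without susceptible replicate 1 (1043 and 1052). Of the 8551 regions with a peak in exactly 3 libraries, 809 (9.46%, 95% Clopper-Pearson interval 8.85 to 10.1%) followed the groups, against 10% if every combination of 3 libraries were equally common. Without Z, W and unplaced sequence the share was 10.1%. Resistant-only regions had a median length of 526 bp, with 253 on macrochromosomes, 94 on intermediate chromosomes, 170 on microchromosomes and 2 on Z. Susceptible-only regions had a median length of 555 bp, with 135, 62 and 92 on these autosome classes.

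**Figure D4:**
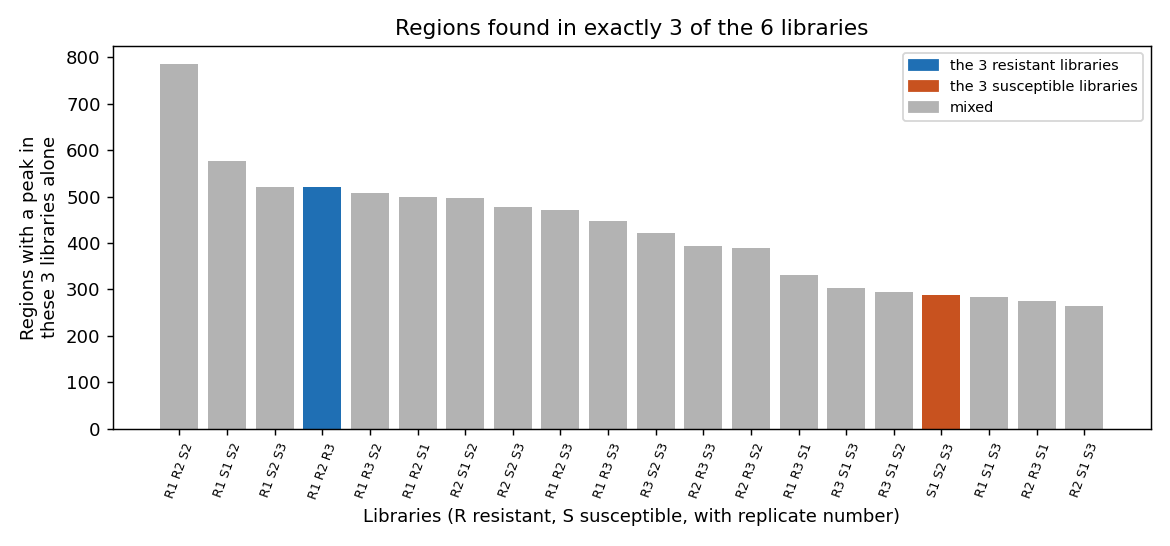
Number of regions with a peak in exactly the 3 libraries named, for each of the 20 choices of 3 libraries. The resistant group has 520 and the susceptible group 289, and the mixed choices range from 265 to 785.

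The highest-ranked resistant-only regions lay close together on chromosome 4. The first, at 85249230 to 85250669 (1440 bp), had scores of 1161.12, 328.58 and 466.56 in resistant replicates 1 to 3, and the nearest peak of a susceptible library was 1056 bp away. The next, at 85257715 to 85259437 (1723 bp), had scores of 680.56, 325.65 and 593.45, with the nearest susceptible peak 1309 bp away. Below these ranked 9:1099071 to 1100047, 2:8755757 to 8756367, 14:15150255 to 15151124, 13:1123113 to 1124519 and 6:22522462 to 22523253. The remaining named regions were 4:15979541 to 15980058, 2:58398030 to 58398691 and 1:45299170 to 45299791. Of these, 2:58398030 to 58398691 was the most isolated, with susceptible peaks no closer than 52149 bp, while the region on chromosome 14 had a susceptible peak 362 bp away.

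Among susceptible-only regions the highest-ranked was 24:3026300 to 3027101 (802 bp), with scores of 264.91, 250.9 and 218.86 in susceptible replicates 1 to 3 and the nearest resistant peak 5545 bp away. It was followed by 4:11593314 to 11593814 (501 bp), with scores of 338.61, 321.96 and 197.08, and 14:10257368 to 10257759 (392 bp), whose nearest resistant peak was 10803 bp away. The others were 15:7017231 to 7017956, 3:39165128 to 39165670, 3:20831487 to 20832166, 6:6487192 to 6487858, 6:16204446 to 16205490, 1:68433208 to 68433547 and 4:17227533 to 17227954. Resistant peaks lay closest, at 302, 594 and 847 bp, to 3:20831487 to 20832166, 4:17227533 to 17227954 and 6:6487192 to 6487858. Peaks in group-only regions had median score percentiles of 20.05 to 27.0 over the 6 libraries, and those of all regions found in exactly 3 libraries had 20.05 to 26.4. The lowest score percentile of the 3 libraries had a median of 9.24 in resistant-only and 10.4 in susceptible-only regions, and it reached 50 in 4 and 2 regions. Mixed choices of 3 libraries gave 0 to 5 such regions, so strong regions of this kind were not particular to the groups. At the pooled median score, 3 of the 10 named resistant-only and 2 of the 10 named susceptible-only regions were found again, and with fixed windows 4 and 3.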

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

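The use of only the 4 libraries with low Z coverage was chosen after seeing the data, and the other alternatives were planned. Over all results and alternatives, 114 values kept their direction or size, 22 changed direction and 21 counts moved by more than 1.5 times. Some of the 114 could not have changed. Named regions are found again by construction when a library is left out. The autosome classes and chromosome 16 are untouched by leaving out Z and W. Resistant libraries had more peaks under every alternative run for peak number. That difference was 972.5 without resistant replicate 1, 1744 without susceptible replicate 1, 1664 without susceptible replicate 3, 5192 without resistant replicate 3 and 5132 without susceptible replicate 2. With equal list lengths the resistant minus susceptible difference turned to -0.791 Mb for covered length and, in kb per Mb, to -0.643 on intermediate chromosomes, -0.694 on macrochromosomes and -0.976 on microchromosomes, an alternative that by construction removes more peaks from the resistant lists. Leaving out 1 library gave -1.44 to 1.75 Mb for covered length, -65.4 to 11.5 bp for mean peak width (positive without susceptible replicate 3) and, in kb per Mb, -0.856 to 2.08 on intermediate chromosomes, -0.657 to 0.891 on macrochromosomes, -2.00 to 2.73 on microchromosomes, -11.8 to 11.9 on Z and -45.0 to 43.0 on W. Signs turned without susceptible replicate 1 (covered length, all 3 autosome classes, W at 17.9), resistant replicate 3 (covered length, W at 43.0), resistant replicate 1 (intermediate at -0.0463, macrochromosomes at -0.408, Z at 5.35), resistant replicate 2 (Z at 4.89), susceptible replicate 2 (W at 22.9) and susceptible replicate 3 (Z at 11.9). The share of regions following the groups was 8.23 to 10.8% with 1 library left out, above the 10% of equal combinations only without resistant replicate 3, and was 10.1% without Z, W and unplaced sequence and 34.0% in the 4 low-Z libraries, where equal combinations give 33.3%. Resistant-only regions numbered 206 at the pooled median score, 236 in fixed windows, 1043 to 1738 with 1 library left out and 2826 in the 4 low-Z libraries. Susceptible-only regions numbered 136, 254, 620 to 1052 and 1698 in the same order, so that they outnumbered resistant-only regions in fixed windows, as they did without susceptible replicate 1 (1052 against 1043) and with equal list lengths (397 against 352), and fewer libraries loosen the definition by construction. Within-group similarity stayed below between-group similarity except in the 4 low-Z libraries, at 0.00123. The cause of the other changes was not tested. The other promoter windows and gene distances meant for promoters and gene lists were not run, since no annotation of galGal4 was used. Unknown depth limits every absence of a peak.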

Other observations

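The tests of Z and W coverage, the block on Z, list length, weak peaks and chromosome 15, the sorting of splits and choices by the libraries with high Z coverage, and the count of neighbours outside Z and W were chosen only after the result was seen. The comparisons with all other groupings of the libraries had been planned, but what they were expected to show was written down only after their results were seen, and the test of neighbouring resistant-only regions over all chromosomes was set before its value was seen. The far end of chromosome Z, from 73 Mb on, held most of the peak-covered length of Z in every library, between 59.7% (resistant replicate 3) and 60.4% (susceptible replicate 1). The block near 27 Mb held 117 peaks in resistant replicate 3, the last ending at 27303151, and 128 in susceptible replicate 3, the last ending at 27284839. In the other libraries it held 26 and 15 (resistant replicates 1 and 2) and 16 and 18 (susceptible replicates 1 and 2), and the last ended at 27172160.

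Resistant replicate 3 and susceptible replicate 3 had the highest Z and the lowest W coverage of their groups. Their covered length outside Z and W, at most 41.5 Mb, lay within the 38.1 to 42.4 Mb of the other libraries. Covered length does not measure depth, so this alone cannot exclude higher depth. Higher depth alone would not lower W coverage, which was 50.2 and 53.3 kb per Mb against 179 to 189 in the other libraries. These W values argue against it as the whole account. Male birds among female birds are a candidate explanation, since the lowest W coverage of the other libraries was 3.36 times the highest in resistant replicate 3 and susceptible replicate 3. However, the labels give no sex and W was not empty in either library. Whether Z copy number alone could account for the excess over Z as a whole stays open. At a doubled score minimum of 160 these libraries kept at least 3578 Z peaks, above the 3238 that any other library had at the deposited minimum, but this bound assumes that scores scale linearly with depth.

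Whether copy number alone could account for the block near 27 Mb also stays open. The lower value of the 2 libraries was 8.12 times the highest of the others there, against at most 3.01 in the other well-covered windows of Z, but the window was picked for its ratio and peak-covered length need not scale with copy number. The male hypermethylated region, a locus of chicken Z methylated in males, may be the source, but the position was not checked against an annotation. The excess there was confined to 1 library of each group.

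Resistant-only regions outnumbered susceptible-only regions over the full lists, at 520 against 289, but not with equal list lengths (352 against 397), in fixed windows (236 against 254) or without susceptible replicate 1 (1043 against 1052). Peaks in group-only regions were weak, with median score percentiles of at most 27.0, against 67.5 to 71.5 in regions of all 6 libraries. All regions of exactly 3 libraries were about as weak, at most 26.4. The group-only median was above theirs in resistant replicate 1 and susceptible replicate 2 and below it in the other libraries. Whether weak peaks near the calling threshold play a part in the excess is thus not settled. At the pooled median score 206 against 136 regions were left. Peak list length stays open as an explanation. Given 1 propensity per library, 518 and 329 regions were expected over all chromosomes, and the observed numbers were 1.004 and 0.879 times these, inside the range of 0.801 to 1.30 among mixed choices of libraries, which Z and W widen. In the same way 479 and 296 regions were expected outside Z and W, and the observed numbers were 1.08 and 0.976 times these, where the mixed choices ranged from 0.870 to 1.07. Outside Z and W the resistant ratio thus left the range set for this explanation, by much less than the SD of 0.0602 among mixed choices. The propensities were fitted to these same counts of regions in exactly 3 libraries and not to list lengths. Ratios near 1 therefore cannot show that list length accounts for the numbers.

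The 20 choices of 3 libraries and the 10 splits are too few for a share under 0.05. As many regions as the 520 resistant-only ones were found in 4 of 20 choices and as many as the 289 susceptible-only ones in 17 of 20, with 785 as the highest other count. Among the 12 choices that hold 1 of the 2 libraries with high Z coverage, as both groups do, these numbers were 2 and 9, with 521 as the highest other count. A share as large as the 9.46% that followed the groups was given by 6 of 10 splits, with 12.7% as the highest other, and a within-group excess of similarity as large as -0.00777 by 7 of 10, with 0.0132 as the highest other. The splits differ in structure, since the 4 that put the libraries with high Z coverage on the same side gave the largest shares (10.8 to 12.7%) and the only positive differences in similarity (0.0113 to 0.0132). Among the 6 that keep them apart, as the groups do, 9.46% was the tied highest share, and without Z and W the real split had the highest, 10.1% against 8.34 to 10.02%, while 2 of the other 5 gave a larger difference in similarity. On chromosome 15, picked as the top chromosome of the real split, 31 of 158 regions (19.6%) followed the groups (Fisher exact test outside Z and W, p = 0.000264, adjusted p = 0.00765 over 29 chromosomes and linkage groups). This test treats regions of the same libraries as independent, so its p-values do not measure the spread between samples. The highest other split gave 14.6% on chromosome 15, but that chromosome was picked for the real split. For 2 of the 9 other splits the top chromosomes were 27 and 28. There 22.9% and 21.8% of such regions followed the split (same Fisher exact test, adjusted p = 0.0164 and 0.0318). Whether resistant-only regions cluster locally stays open. Of them 6.73% had another within 20000 bp, and 3 other choices of libraries gave more, with 9.90% as the highest. Local clusters had been set beforehand to require a value above all 19 other choices, and this was not met. The bound set for that test was not apt, since it made no allowance for neighbours on Z, without which (and W) the 9.90% fell to 2.08%, or for the number of regions, with which the value rose over the 19 other choices outside Z and W (Spearman correlation 0.843). Outside Z and W 6.76% of resistant-only regions had such a neighbour (95% Clopper-Pearson interval 4.75 to 9.27%), against at most 6.38% in the 17 choices with no more regions, 6.07% in the choice with 560 regions and 7.12% in the choice with 772. The interval is too narrow, since it treats regions as independent while neighbouring regions count each other.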
